A study of Mus musculus with 15 samples.

How the data were processed

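Total RNA of vascular tissue from C57BL/6 mice aged 10 weeks was sequenced after removal of ribosomal RNA, per the labels, in 3 groups of 5 libraries (NS, AngII and Lien). The extraction note of the labels speaks of heart tissue where the sample labels give vascular tissue, and this was left unresolved. The aligner, the assembler, the quantifier, the genome build and the annotation are not given in the sources used here, and limma is named among the submitters' processing steps without a version or a role.

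The deposited table holds 131437 transcripts, of which 101208 carry an Ensembl identifier and 30229 carry an assembly name with no public identifier or position. Neither the header nor the labels name the unit. The deposited values were read as FPKM (fragments scaled to the length of the transcript and to the fragments of the library), since they are not whole, belong to transcripts and sum to 477095 to 569546 per library (median 515411), which rules out TPM over these transcripts. Low values (at most 0.3 FPKM × kb, transcripts of at least 1000 bases) fell on evenly spaced steps in 99.1% to 99.7% of cases, within 0.05 of a step. The implied depth of 1.57e+07 to 1.93e+07 fragments per library follows from reading the values as FPKM and the commonest low value, 4 steps, as 1 fragment. With 1 step as 1 fragment it would be 4 times as high, and the labels state no depth. No table of fragment counts is given in the sources used here, so no counting intervals are given.

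The Ensembl transcripts were matched to GENCODE M21 (GRCm38), whose version may differ from the one the authors used. Of these 99965 were found and 1243 were not, which held 0.571% to 0.990% of the sum of values per library. Transcripts were summed to 32930 genes, and 71 genes that share a symbol with another gene were told apart by identifier. Transcripts without a public identifier held 11.0% to 17.0% of the sum and stayed out of the gene values. Mitochondrial transcripts held 5.18% to 22.0%. The script used all 15 sample columns.

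Genes with at least 0.5 FPKM in at least 5 libraries were tested, 15586 in all, on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. A single fit of the 3 group means over all 15 libraries left 12 residual degrees of freedom, and the 3 differences between groups were tested with empirical Bayes variances (trend and robust options), two-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. The design, fixed before the data were examined, named a test for counts and this limma test for FPKM, and the latter applied. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

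Of 46 gene lists fixed in advance, 44 had at least 3 measured genes, and the lists for airway epithelium and X inactivation did not. Lists were tested with fry of limma, which asks whether the genes of a list move on balance one way (directional p) or change in either direction, adjusted over the 44 lists in each comparison. The camera test of limma with an estimated correlation between genes, and with a preset correlation of 0.01, was run beside it. For the lists described, the genes were also adjusted over the list alone.

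Genes were named by a rule fixed in advance. It took, in each comparison, up to 8 genes with the largest rise and 8 with the largest fall among those called with a mean of at least 1 FPKM over all libraries and every library of one group beyond the median of the other, leaving out pseudogenes, receptor segments and genes without a standard symbol. It added up to 4 members of each list described with the smallest adjusted p among those called, or the 2 with the highest mean where none was called, and, in every comparison, a fixed set of genes of TGF-β signalling, MAP kinases, collagens, smooth muscle actin and the angiotensin receptor, not all of which are given here. Where fewer than 10 genes were called, the 10 with the smallest p were named.

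Genes that moved back were those called in AngII against NS and in Lien against AngII with opposite signs. Since both differences share the AngII libraries, 100 simulations of unchanged groups were run, and each of the 10 divisions of the AngII libraries into 2 and 3 was fitted. The tests were tried on simulated data, in 5 runs with 200 changed genes among the 15586 of AngII against NS. They recovered 55.4% of genes changed by a fold of 2 and 88.6% of those changed by a fold of 4, with 6.01% false calls. Where nothing had changed, they called 0.2 genes on average. These rates describe the simulated data alone. Of 100 random splits of the AngII and NS libraries, the real one included, 3 called at least 12 genes, up to 885. Of 100 such splits of the Lien and AngII libraries, 10 called at least 2 genes, up to 1480. For Lien and NS the highest split besides the real one called 4. The simulated 0.2 therefore does not describe every regrouping of the real libraries.

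Alternatives covered the trend option, quantile normalization, scaling libraries to one median, no filter, a pseudocount of 0.1, fits of 2 groups alone, library weights, covariates for neighbouring tissue, each library left out in turn and an absolute log2 fold change of at least 1. Alternatives chosen after seeing the data were covariates for Hox genes and for cardiac, nerve and lymphocyte genes, a fit without NS 3, AngII 9 and Lien 13, a fit of single transcripts, and both scalings for the lists.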

Results

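RNA was measured by sequencing in vascular tissue of C57BL/6 mice at 10 weeks of age, in 3 groups of 5 libraries each. The NS group is labelled as normal, the AngII group as hypertensive, and the Lien group as hypertensive with Lien added. AngII stands for angiotensin II, a peptide hormone that raises blood pressure and drives vessel wall thickening. Lien is read from the title of the series as liensinine, an alkaloid of lotus seed embryos. That title gives the question as well, which is whether liensinine lessens the remodeling of vessels under angiotensin II and whether MAPK and TGF-β/Smad signalling take part. The deposited values are read as FPKM per transcript and were summed here per gene. Low values fell on evenly spaced steps in 99.1% to 99.7% of cases, within 0.05 of a step, and the commonest low value, 4 steps, taken as 1 fragment corresponds to 1.57e+07 to 1.93e+07 fragments per library. The labels do not say whether each library came from a separate mouse. The limma p-values below therefore set differences of group means against the spread between libraries within groups, not necessarily between mice.

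The libraries held different amounts of RNA from neighbouring tissues, and most of these differences did not follow the groups. Skeletal muscle genes averaged 9.41 on the log2(FPKM + 1) scale in NS 3 and 6.35 in AngII 9, against at most 2.62 in the other libraries. Brown adipocyte genes averaged from 3.74 in Lien 11 to 6.27 in Lien 15, and the brown adipocyte gene Ucp1 stood at 143 to 1921 FPKM. RNA of brown fat was thus present in every library, and the gene results below do not tell fat from vessel wall. Cardiomyocyte genes averaged 5.30 in NS 1, 6.15 in NS 5 and 5.63 in AngII 8. They averaged 2.74 to 3.91 in NS 4, Lien 12, Lien 13 and Lien 14, and 0.59 to 1.45 in the remaining libraries. Genes of nerve and Schwann cells averaged 3.32 to 4.47 in NS 2, NS 3, AngII 6, AngII 7, AngII 9 and Lien 11, and 1.09 to 2.29 in the other 9 libraries. Those 6 libraries were also the 6 with the highest mean of Hox genes of paralogue groups 9 to 13 (1.72 to 2.41, against 0.32 to 1.40), the genes that mark posterior positions along the body axis. T cell genes averaged 3.80 in AngII 7 and 3.94 in AngII 9, and B cell genes 4.89 and 5.63. The mesothelial list was the exception, at 1.72 to 2.74 in NS, at 0.582 to 1.09 in AngII apart from 2.44 in AngII 8, and at 0.777 to 1.87 in Lien. The contractile smooth muscle list averaged 4.55 in Lien 13 and 5.76 to 6.94 elsewhere, and Acta2, smooth muscle actin, stood at 188 FPKM in Lien 13. The first principal component of all genes held 34.2% of the variance. It lay at 33.9 to 70.0 in the 6 libraries highest in nerve and posterior Hox genes and at -44.0 to -15.2 in the other 9. These 6 were 2 NS, 3 AngII and 1 Lien, and the main fit held no term for this split. Pearson correlations between libraries, taken across genes, ran from 0.853 to 0.958, so no library appeared to have been deposited a second time.

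**Figure D1:**
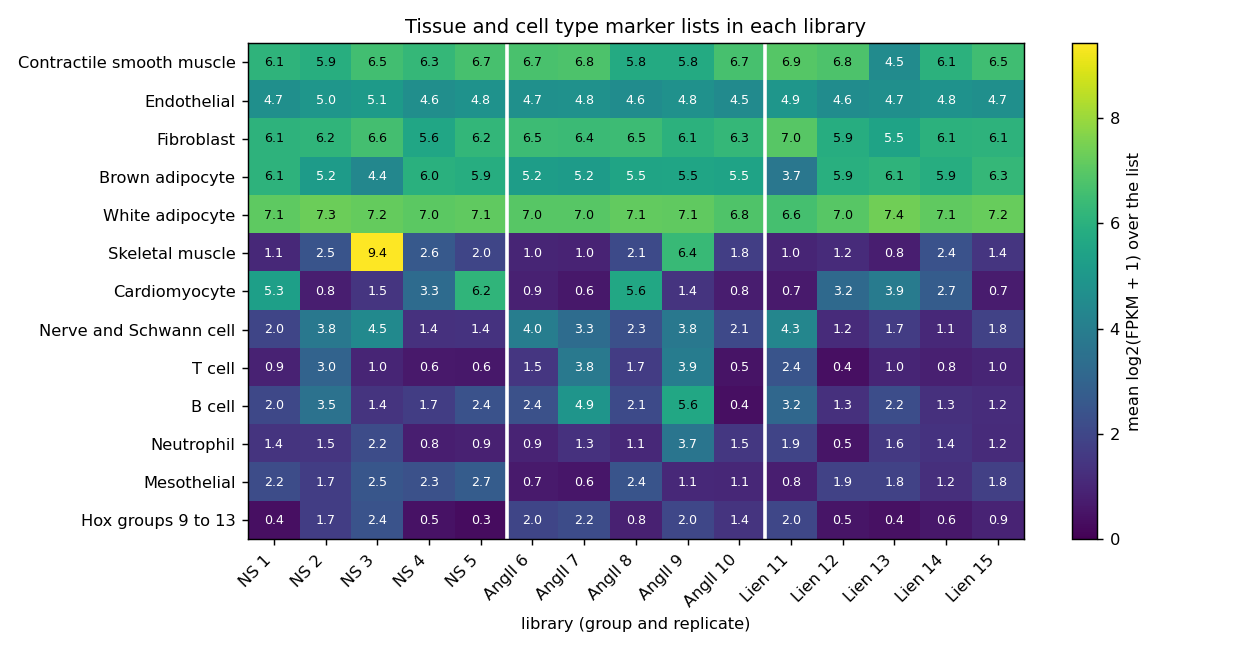
Mean log2(FPKM + 1) of the marker genes of each tissue or cell type list (vertical axis) in each of the 15 libraries (horizontal axis, group and replicate), given by colour and printed in each cell. Skeletal muscle genes reach 9.41 in NS 3, and the Hox genes of groups 9 to 13 and the nerve list are highest in the same 6 libraries, which come from all 3 groups.

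The first comparison asks what differed in the AngII group. Of 15586 genes tested with limma, 8 fell and 4 rose in AngII relative to NS at an adjusted p under 0.05. Dusp10, a phosphatase that switches off the p38 and JNK kinases, fell from 18.4 ± 3.9 FPKM in NS to 5.43 ± 1.46 in AngII (SD, n = 5 each), a log2 fold change of -1.60 (SE 0.21, limma adjusted p = 0.0124). Kcna5, a voltage-gated potassium channel of smooth muscle, rose from 5.03 ± 1.27 to 11.9 ± 1.43 FPKM (log2 1.12, SE 0.16, limma adjusted p = 0.0248). Gadd45b, a stress-inducible regulator of p38 and JNK signalling, rose from 12 ± 2.36 to 29.5 ± 6.23 FPKM (log2 1.22, SE 0.19, limma adjusted p = 0.031). Irs2, an adaptor of the insulin receptor, fell from 44.5 ± 12.9 to 17.3 ± 2.75 FPKM (log2 -1.28, SE 0.21, limma adjusted p = 0.038). For each of the 12 genes, every library of one group lay beyond the median of the other group.

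The other 8 genes were spread over several functions. B3gat2, a glucuronyltransferase, was listed at 0.93 to 1.35 FPKM in the NS libraries and at 0 to 0.261 FPKM in the AngII libraries (log2 -1.02, SE 0.12, limma adjusted p = 0.00549), a level near the floor of these libraries, where a pseudocount of 0.1 gave a log2 of -3.08. Adamts4, a protease that cleaves the matrix proteoglycans aggrecan and versican, fell from 3.33 ± 0.60 to 0.906 ± 0.199 FPKM (log2 -1.18). Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, fell from 7.52 ± 1.98 to 3.23 ± 0.61 FPKM (log2 -0.99, limma adjusted p = 0.0461). Lower values were also found for Dlc1 (log2 -0.92) and for Bcl6b (-0.80) and Tcf15 (-0.90), transcription factors of endothelium. Klf15, a transcription factor induced by glucocorticoids, rose from 18.3 ± 5.6 to 39.3 ± 3.59 FPKM (log2 1.11), and Mc5r, a melanocortin receptor, from 0.838 ± 0.139 to 2.98 ± 0.46 FPKM (log2 1.11). Dusp10 lies on chromosome 1 from 184013302 to 184075636, Kcna5 on chromosome 6 from 126532551 to 126535412 and B3gat2 on chromosome 1 from 23761753 to 23849158, each spanning the whole annotated gene with its introns (GRCm38).

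Among the 26 measured immediate early genes and MAPK feedback inhibitors, 2 fell (Dusp10 and Spry4) and the remaining 24 did not pass the test over all genes. Adjusted over the list alone, 7 were lower and 1 was higher. Those besides the 2 named were Dusp4 (log2 -1.18), Atf3 (-1.10), Fosl2 (-0.66), Dusp6 (-0.53) and Spry2 (-0.38) on the lower side and Spry1 (0.81) on the higher side, picked out after their values were seen. The list as a whole changed in mixed directions (fry either-direction adjusted p = 1.8e-08) and had no common direction (fry adjusted p = 0.609, 12 genes higher and 14 lower, median log2 -0.07). None of the 27 genes of the MAPK cascade itself passed the test (fry adjusted p = 0.816), and their median log2 was 0.07 as deposited but -0.06 after quantile normalization and -0.08 after scaling libraries to one median. Mapk3 stood at 75.1 ± 24.8 FPKM in NS and 83.6 ± 25.2 in AngII, Mapk8 at 6.10 ± 0.94 and 6.58 ± 0.91, Mapk14, which encodes p38α, at 22.2 ± 6.75 and 13.7 ± 3.74, and Mapkapk2, its substrate kinase, at 109.7 ± 26.4 and 104 ± 12.6 (SD, n = 5 each).

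No gene of TGF-β signalling passed the test between AngII and NS. Tgfb1 stood at 17.5 ± 5.32 FPKM in NS and 26.7 ± 11.2 in AngII (log2 0.53, SE 0.30, limma adjusted p = 0.732), and its receptors Tgfbr1 and Tgfbr2 differed by 0.53 and 0.12. The signal transducers Smad2, Smad3 and Smad4 differed by 0.09, 0.07 and 0.17, and the inhibitory Smad7 by 0.74 (SE 0.30, limma adjusted p = 0.676). Of the 25 components 18 had higher and 7 lower values (fry adjusted p = 0.646, median log2 0.12), but with either of the 2 scalings 12 were higher and 13 lower. Ltbp3, which binds latent TGF-β, differed by 0.26. Of 16 target genes 10 were on the higher side (fry adjusted p = 0.816, median 0.30), among them Ccn2, connective tissue growth factor, at 388 ± 48.9 and 658 ± 359 FPKM. In neither list did a gene pass adjusted over the list alone.

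Most matrix genes lay on the higher side in AngII without passing the test. Col1a1 stood at 170.3 ± 122 FPKM in NS and 317 ± 109 in AngII (log2 1.23, SE 0.61, limma adjusted p = 0.708), Col1a2 at 241 ± 142 and 431 ± 108, Col3a1 at 218 ± 116 and 355 ± 114, and the proteoglycan Bgn at 502 ± 65.8 and 761 ± 296. Of 24 fibrillar collagen and matrix genes 22 were higher (fry adjusted p = 0.646, median log2 0.37), and 18 and 19 with the 2 scalings. Acta2 differed by 0.09 (SE 0.57) and Tagln, another contractile protein, by 0.12, and the contractile list of 16 genes had a median of 0.01 (fry adjusted p = 0.918), which turned to -0.10 and -0.15 with the scalings. The synthetic smooth muscle list of 14 genes had a median of 0.42 (fry adjusted p = 0.646), with the calcification inhibitor Mgp at 0.66 and the intermediate filament gene Vim at 0.70. Of 15 matrix proteases and inhibitors 1 fell, Adamts4, and 14 did not pass (fry adjusted p = 0.937). Of these 4 lists Adamts4 was again the 1 gene that passed adjusted over the list alone.

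Genes of the glucocorticoid response were mostly higher in AngII, at a directional fry adjusted p of 0.0558, past the threshold neither there nor with an estimated correlation (camera adjusted p = 0.332). Of 14 genes 11 were higher, with a median log2 of 0.51, and the either-direction test passed (fry adjusted p = 7.87e-05). There were 3 genes higher adjusted over the list alone, Ddit4 (1.38), Tsc22d3 (1.34) and Mt2 (0.90), and 1 was lower, Sgk1 (-0.40), all named after their values were seen. The 2 members with the highest level were Mt1, a metallothionein (log2 0.67), and Pdk4, a kinase that inhibits pyruvate dehydrogenase (-0.51). The directional p came to 0.026 without NS 3 and to 0.00794 without AngII 7, while the other 13 fits without 1 library did not pass (adjusted p up to 0.196). It also passed with muscle and fat covariates (fry adjusted p = 0.0272), library weights (0.0281) and cardiac, nerve and lymphocyte covariates (0.0017). With the preset correlation of camera included, the list passed in 6 of 24 alternatives.

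No member of the inflammation, renin-angiotensin, growth factor and endothelial lists passed over all genes. Nfkbia, the inhibitor of NF-κB, stood at 60.1 ± 14.5 FPKM in NS and 118 ± 23.7 in AngII (log2 0.97, SE 0.19, limma adjusted p = 0.0833) and was the 1 inflammation gene of 15 that passed adjusted over the list alone, while the chemokine Cxcl12 differed by 0.09 (fry adjusted p = 0.646). Cldn5, the tight junction protein of endothelium, stood at 224 ± 35 and 107 ± 21 FPKM (log2 -1.06, SE 0.21, limma adjusted p = 0.0833) and was the 1 of 15 endothelial genes that passed adjusted over the list alone. Pecam1, a general endothelial marker, differed by 0.01, and the endothelial list had a median of -0.01 (fry adjusted p = 0.642), or -0.14 and -0.17 with the scalings. In the renin-angiotensin list of 10 genes Ace differed by 0.19, Atp6ap2 by 0.21 and Agtr1a, the angiotensin II receptor, by -0.25 (fry adjusted p = 0.917), and in the growth factor list of 18 genes Vegfa differed by -0.52 and Angptl4 by -0.12 (fry adjusted p = 0.816). No gene of these last 2 lists passed adjusted over the list alone.

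With limma, 1097 genes had an unadjusted p under 0.05 against 779 expected by chance, 847 of them higher, and the median of all genes lay 0.12 higher in AngII on the log2 scale, a value moved by -0.13 with quantile normalization and by -0.12 with scaling libraries to one median, which called 6 genes (1 higher and 5 lower). Small differences had no settled sign, among them those of Mapk3, Mapk8, Smad2, Smad3, Tgfbr2, Acta2, Tagln, Cxcl12 and Pecam1, which turned with at least 1 of the scalings. Leaving out 1 library left 1 gene without NS 1 or AngII 8, 2 without NS 2, NS 4 or AngII 7, 3 without AngII 6, 4 without NS 5 or AngII 9 and 6 without AngII 10, and B3gat2 alone of the 12 kept its call in all 15 of these fits. Dusp10 had an adjusted p of 0.058 without NS 1 and 0.0644 without AngII 8. Kcna5 lost its call without NS 1 (0.0886), NS 2 (0.0856), NS 4 (0.086), NS 5 (0.0532), AngII 6 (0.0925), AngII 7 (0.0558) or AngII 8 (0.0725), and Gadd45b without NS 1 (0.0886), NS 2 (0.073), NS 4 (0.114), NS 5 (0.0815), AngII 6 (0.0945), AngII 7 (0.0927), AngII 8 (0.0725) or AngII 9 (0.096). Each of the other 8 (Adamts4, Bcl6b, Dlc1, Irs2, Klf15, Mc5r, Spry4 and Tcf15) lost its call without any 1 of NS 1, NS 2, NS 4, AngII 7, AngII 8 and AngII 9, with an adjusted p of up to 0.155 for Spry4 without AngII 7, while Cldn5 passed without Lien 13 (0.0441).

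**Figure D2:**
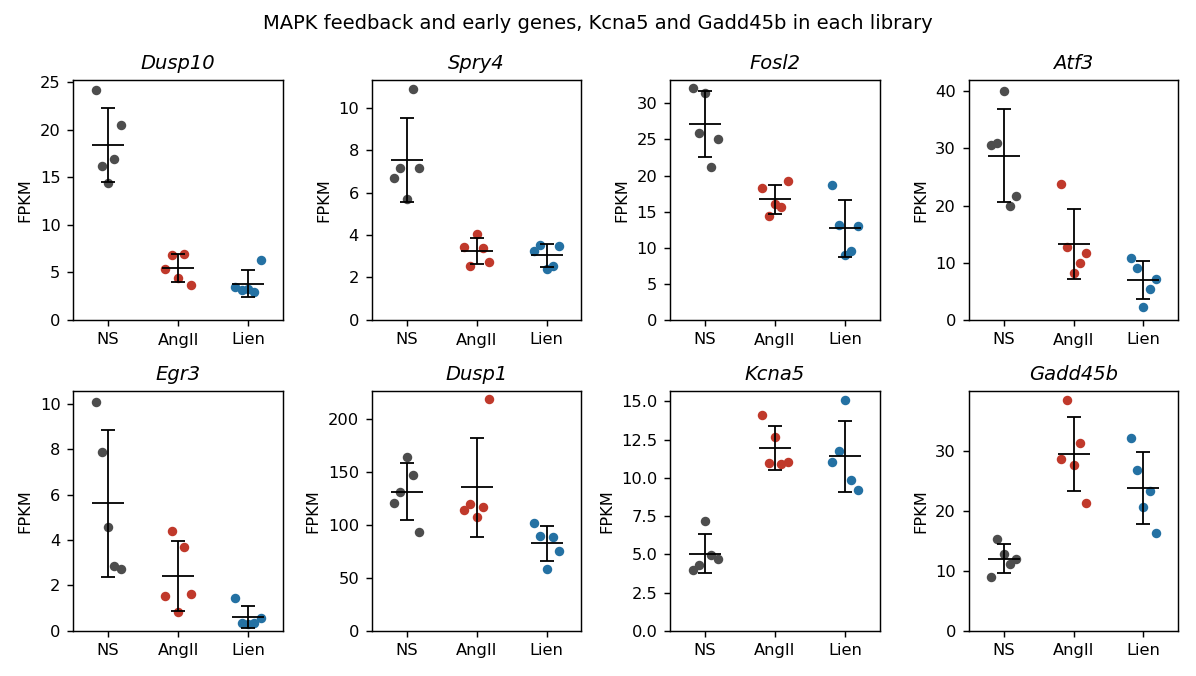
FPKM (vertical axis, linear from 0) of 6 MAPK feedback and early genes and of Kcna5 and Gadd45b in each library of NS, AngII and Lien, with the mean (bar) and SD (whiskers) of 5 libraries. Dusp10 lies at 14.3 FPKM or above in every NS library and at 6.97 or below in every AngII and Lien library.

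The second comparison asks what differed when Lien was added to AngII. With limma, 2 of 15586 genes rose in Lien relative to AngII and none fell, while 997 had an unadjusted p under 0.05, 164 of them higher and 833 lower. B4galt1, which adds galactose to glycoproteins, rose from 4.33 ± 0.41 FPKM in AngII to 25.4 ± 4.07 in Lien (SD, n = 5 each), a log2 fold change of 2.3 (SE 0.15, limma adjusted p = 1.9e-06), and the 5 Lien libraries at 21.7 to 32.2 FPKM lay above all 10 others. B3gat2 stood at 0 to 0.261 FPKM in the AngII libraries and at 0.764 to 1.34 in the Lien libraries (log2 0.88, or 2.81 with a pseudocount of 0.1; SE 0.12, limma adjusted p = 0.0186). B4galt1 lies on chromosome 4 from 40804602 to 40854005, on the minus strand (GRCm38). An assembled transcript with no public identifier showed the opposite profile, 25.3 to 31.7 FPKM in the 10 NS and AngII libraries and 0 to 2.32 FPKM in the Lien libraries.

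**Figure D3:**
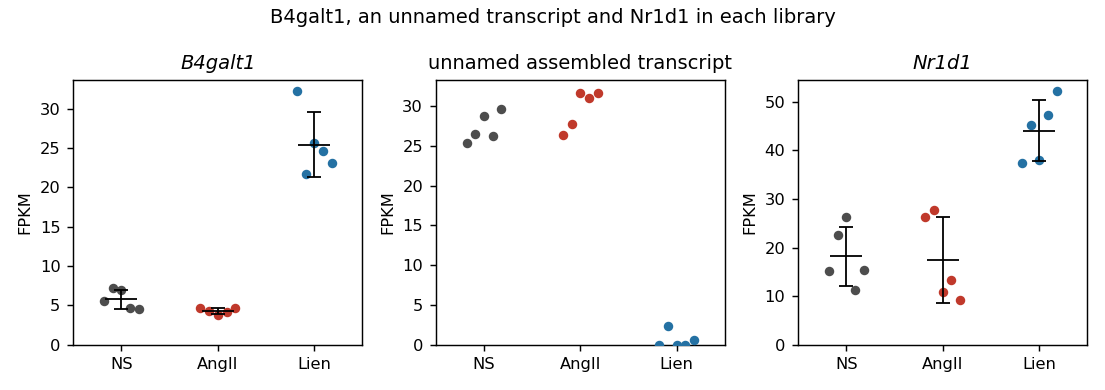
FPKM (vertical axis, linear from 0) of B4galt1, of an assembled transcript with no public identifier and of Nr1d1 in each library of NS, AngII and Lien, with the mean (bar) and SD (whiskers) of 5 libraries for the 2 genes. B4galt1 is at 21.7 FPKM or above in every Lien library and at 7.18 or below in every other library, while the unnamed transcript is at 2.32 or below in Lien and at 25.3 or above elsewhere.

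Since fewer than 10 genes passed, the 10 with the smallest p are named, and the other 8 did not pass. Klf2, a flow-responsive transcription factor of endothelium, stood at 86.8 ± 21 FPKM in AngII and 41.8 ± 11.9 in Lien (log2 -1.05, SE 0.19, limma adjusted p = 0.238), and Bcl6b at 6.09 ± 0.80 and 3.38 ± 0.41 (log2 -0.69, limma adjusted p = 0.175). Crbn, the substrate receptor of a ubiquitin ligase, stood at 25.8 ± 6.68 and 12.8 ± 1.57 FPKM (log2 -0.91, limma adjusted p = 0.378). Nr1d1, a repressor in the circadian clock, stood at 17.5 ± 8.79 and 44.1 ± 6.3 FPKM (log2 1.41, limma adjusted p = 0.378). The log2 differences of the remaining 4 were -1.24 for Eif2b3, a subunit of a translation initiation factor, -0.54 for the kinase gene Cdk17, 0.67 for Creld1 and 1.41 for Zfp532. Crbn passed without AngII 9 (adjusted p = 0.00787) and Klf2 without Lien 11 (adjusted p = 0.0403).

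The MAPK feedback and early genes fell as a list, with 25 of 26 lower in Lien than in AngII and a median log2 of -0.48 (fry adjusted p = 0.0356). The list did not pass with an estimated correlation (camera adjusted p = 0.577). No single member passed over all genes. Adjusted over the list alone 1 member was lower, Phlda1 (log2 -1.0), named after its value was seen. Dusp1, a phosphatase of MAP kinases, stood at 135 ± 46.6 FPKM in AngII and 82.4 ± 16.6 in Lien (log2 -0.68), and Nr4a1, an immediate early nuclear receptor, at 43.7 ± 18.4 and 26.7 ± 11.3 (log2 -0.67). Marker lists of other tissues and cells went both ways in the same comparison, with medians of -0.93 for nerve (12 of 12 genes lower), -1.22 for skeletal muscle (12 of 12), -1.18 for T cells (14 of 14) and -1.04 for B cells (11 of 12), and of 0.55 for cardiomyocytes (9 of 12 higher), 0.39 for mesothelium (7 of 8), 0.11 for white and 0.10 for brown adipocytes. The median of all genes was -0.13, and with quantile normalization and scaling to one median, which move it by 0.15 and 0.18, the list stayed on the lower side, 23 of 26 genes with each, but lost its call (fry adjusted p = 0.232 and 0.779).

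The MAPK cascade genes (20 of 27 lower, fry adjusted p = 0.802, median log2 -0.13) and the TGF-β and Smad components (21 of 25 lower, fry adjusted p = 0.802, median -0.22) did not pass. With the 2 scalings 15 and 8 of the cascade genes and 17 and 13 of the components were lower. Mapk3 differed by -0.21, Mapk8 by -0.25, Mapk14 by 0.05 and Mapkapk2 by -0.04. Tgfb1 stood at 26.7 ± 11.2 FPKM in AngII and 19.4 ± 8.67 in Lien (log2 -0.43, SE 0.30, limma adjusted p = 0.74). Smad2, Smad3, Smad4 and Smad7 differed by 0.08, -0.26, -0.24 and -0.22, Tgfbr1 by -0.32 and Tgfbr2 by -0.20. The TGF-β target genes had a median of -0.20 (11 of 16 lower, and 8 after scaling to one median; fry adjusted p = 0.931), with Ccn2 at -0.36 and Tagln at -0.12. Mapk3, Mapkapk2 and Tgfbr2 changed sign with at least 1 of the scalings. In these 3 lists no gene passed adjusted over the list alone.

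No matrix or smooth muscle gene passed between Lien and AngII. Col1a1 stood at 317 ± 109 FPKM in AngII and 355 ± 269 in Lien (log2 -0.06, SE 0.61), Col3a1 at 355 ± 114 and 397 ± 290 (log2 -0.05, SE 0.43), and Col1a2 and Bgn differed by -0.10 and -0.19. The fibrillar collagen and matrix list had 17 of 24 genes higher and a median of 0.18 (fry adjusted p = 0.931). Acta2 differed by -0.17 (SE 0.57). The contractile list had a median of -0.17, the synthetic list, with Mgp at -0.004 and Vim at -0.27, of -0.25 and the matrix protease list, with Timp2 at -0.38 and Timp3 at -0.13, of -0.04, at fry adjusted p of 0.931, 0.931 and 0.937. The inflammation list had a median of -0.36 (11 of 15 lower, fry adjusted p = 0.802), with Nfkbia at -0.36 and Cxcl12 at -0.39. Medians were -0.20 for the glucocorticoid response (fry adjusted p = 0.802), with Mt1 at -0.23 and Pdk4 at 0.43, and -0.03 for endothelium (0.931), with Cldn5 at -0.41 and Pecam1 at -0.02. They were -0.09 for the renin-angiotensin list (0.931), with Ace at 0.09, Atp6ap2 at -0.27 and Agtr1a at -0.12, and -0.11 for growth factors (0.802), with Angptl4 at -0.04 and Vegfa at 0.13. In these 9 lists no gene passed adjusted over the list alone. After scaling to one median the medians of the contractile, matrix protease, glucocorticoid, endothelial, renin-angiotensin and growth factor lists turned positive, as did the differences of Col1a1, Col1a2, Col3a1 and Acta2 with at least 1 scaling.

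**Figure D4:**
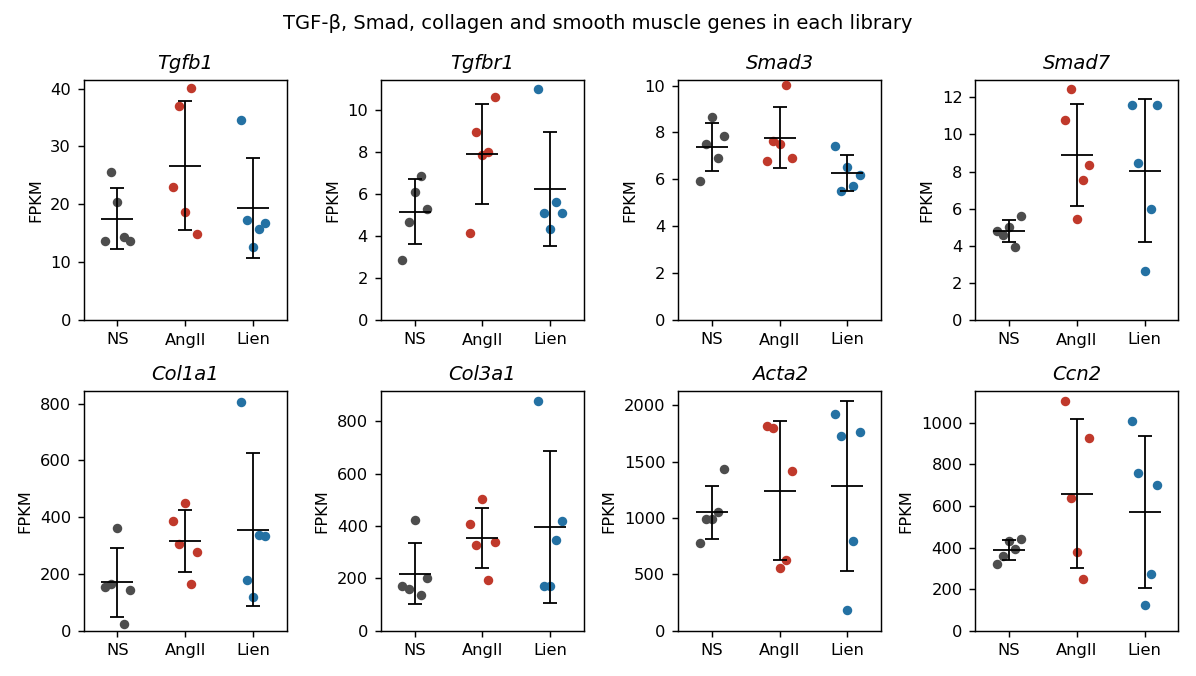
FPKM (vertical axis, linear from 0) of TGF-β signalling genes, fibrillar collagens, Acta2 and Ccn2 in each library of NS, AngII and Lien, with the mean (bar) and SD (whiskers) of 5 libraries. None of the 8 genes passed the test in any comparison, and Col1a1 spread widest in Lien, at 355 ± 269 FPKM.

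B3gat2 lost its call without AngII 6 (adjusted p = 0.0837), AngII 7 (0.108), AngII 9 (0.0598), AngII 10 (0.0879), Lien 14 (0.0505) or Lien 15 (0.0842), which left 1 gene called in 5 of these fits, and B4galt1 kept its call in each of 26 other fits. The MAPK feedback list lost its call without NS 4 (fry adjusted p = 0.0513), AngII 6 (0.0762), AngII 7 (0.107), AngII 8 (0.0757), AngII 9 (0.107), AngII 10 (0.0912), Lien 12 (0.0882), Lien 13 (0.11), Lien 14 (0.114) or Lien 15 (0.0896).

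The third comparison asks what differed between the Lien group and NS. With limma, 31 genes fell and 5 rose in Lien relative to NS. Dusp10 fell from 18.4 ± 3.9 to 3.80 ± 1.39 FPKM (SD, n = 5 each; log2 -2.03, SE 0.21, limma adjusted p = 0.000419). Slc25a25, a mitochondrial ATP-magnesium carrier, fell from 22.5 ± 7.55 to 4.62 ± 1.54 FPKM (log2 -2.03, SE 0.29, limma adjusted p = 0.00984). Bcl6b fell from 11.3 ± 0.8 to 3.38 ± 0.41 FPKM (log2 -1.49, SE 0.12, limma adjusted p = 2.15e-05) and Cldn5 from 224 ± 35 to 82.4 ± 23.7 FPKM (log2 -1.47, SE 0.21, limma adjusted p = 0.00984). Apold1, an early response gene of endothelium, had the largest log2 difference of the named genes, -4.34 (SE 0.66, limma adjusted p = 0.0136). It stood at 25.9 to 59.0 FPKM in the NS libraries, and in Lien it was listed at 3.08 and 3.30 FPKM in replicates 12 and 13 and at 0 in the other 3, so its fold rests on the pseudocount. With a pseudocount of 0.1 the difference of Apold1 was -6.44 and its call was lost (adjusted p = 0.0848), as it was with cardiac, nerve and lymphocyte covariates.

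Further genes that fell included Atf3, a stress-induced transcription factor (28.7 ± 8.13 to 6.91 ± 3.31 FPKM, log2 -1.99), Egr3, an immediate early transcription factor (log2 -1.95), and Sik1, a salt-inducible kinase (log2 -1.84). Ptger4, a prostaglandin E2 receptor, fell by 1.54 on the log2 scale and Fam172a by 1.58. Adamts4 fell from 3.33 ± 0.60 to 0.901 ± 0.503 FPKM (log2 -1.21, limma adjusted p = 0.0116), Fosl2 by 1.07, Spry4 by 1.06 and Sgk1, a glucocorticoid-induced kinase, by 0.74. Of the genes that rose, B4galt1 went from 5.76 ± 1.25 to 25.4 ± 4.07 FPKM (log2 1.97, SE 0.15, limma adjusted p = 1.59e-05), with the opposite profile of the unnamed transcript given above, and Kcna5 from 5.03 ± 1.27 to 11.4 ± 2.3 FPKM (log2 1.04, limma adjusted p = 0.0136). Tnks2, a poly-ADP-ribosyltransferase, rose from 6.22 ± 3.91 to 18.6 ± 1.9 FPKM (log2 1.56) and Spsb1, an adaptor of a ubiquitin ligase, from 17.4 ± 3.61 to 39.0 ± 11.3 FPKM (log2 1.09). The fifth was a ribosomal protein pseudogene, whose fragments may not be told apart from its parent gene.

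Of the 26 measured MAPK feedback and early genes 6 fell, Dusp10, Atf3, Egr3, Fosl2, Spry4 and Dusp6, none rose and 20 did not pass. Lower values were found for 25 of the 26, with a median log2 of -0.56 (fry adjusted p = 0.00211). The list also passed with an estimated correlation (camera adjusted p = 0.0249) and in all 15 fits that left out 1 library (fry adjusted p at most 0.0103). Adjusted over the list alone 13 genes were lower, among them Nr4a1 (log2 -1.96), Dusp4 (-1.09), Dusp5 (-0.95) and Dusp1 (-0.66), and 1 was higher, Spry1 (0.54). Dusp6, these 5 and Bcl6b in this comparison were named after their values were seen. Between the same groups the median was -0.58 for the nerve list, -2.14 for skeletal muscle, -1.21 for cardiomyocytes (11 of 12 lower) and -0.92 for mesothelium (8 of 8 lower).

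**Figure D5:**
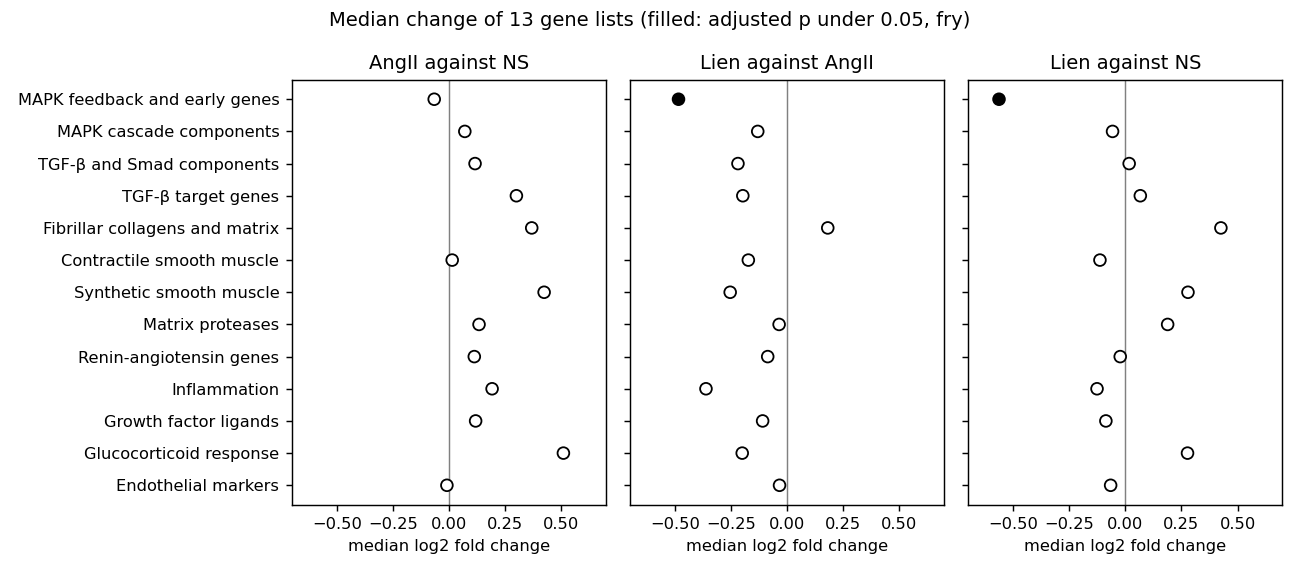
Median log2 fold change (horizontal axis) of the members of 13 gene lists (vertical axis) in each comparison, with filled points for lists with a fry adjusted p under 0.05. The MAPK feedback and early genes are the 1 filled list in Lien against AngII (median -0.48) and in Lien against NS (median -0.56), and with an estimated correlation it passes in the latter alone (camera adjusted p = 0.577 and 0.0249).

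No gene of the MAPK cascade and TGF-β lists passed over all genes between Lien and NS. The MAPK cascade list had a median of -0.06 (0.01 after scaling to one median; fry adjusted p = 0.883), with Mapk3 at -0.05, Mapk8 at -0.16, Mapk14 at -0.59 and Mapkapk2 at -0.08, and 1 gene lower adjusted over the list alone, Map2k6 (log2 -0.89), an activator of p38, named after its value was seen. The TGF-β and Smad components had a median of 0.02 (fry adjusted p = 0.945), with Tgfb1 at 0.10, Tgfbr1 at 0.21, Tgfbr2 at -0.08, Smad2 at 0.17, Smad3 at -0.20, Smad4 at -0.06, Smad7 at 0.52 and Ltbp3 at 0.25. The TGF-β targets had a median of 0.07 (fry adjusted p = 0.945), with Ccn2 at 0.21. Neither TGF-β list held a gene that passed adjusted over the list alone.

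Of the matrix genes Col1a1 stood at 170.3 ± 122 FPKM in NS and 355 ± 269 in Lien (log2 1.17, SE 0.61, limma adjusted p = 0.751), Col1a2 differed by 0.98, Col3a1 by 0.71 and Bgn by 0.31, and 21 of the 24 were higher (median 0.43, fry adjusted p = 0.553). Acta2 differed by -0.08, Tagln by -0.002, Mgp by 0.66 and Vim by 0.44, and the contractile and synthetic lists had medians of -0.11 and 0.28 (fry adjusted p = 0.945 for each). Of the synthetic genes 1 was higher, S100a4 (log2 1.59), and 1 lower, Klf4 (-0.71), adjusted over the list alone. Among the matrix proteases Adamts4 fell and Timp4 (0.61) was higher adjusted over the list alone, and the list changed in mixed directions (fry either-direction adjusted p = 0.0167). S100a4, Klf4 and Timp4 were named after their values were seen.

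Of 15 endothelial genes 1 fell, Cldn5, and the list had a median of -0.07, or 0.01 after scaling to one median, with no common direction (fry adjusted p = 0.533, either direction 0.00258). Of 14 glucocorticoid response genes 1 fell, Sgk1, while 10 were higher (median 0.28, fry adjusted p = 0.533, either direction 4.57e-05), and adjusted over the list alone Zbtb16 (1.49) and Ddit4 (0.89) were higher and Sgk1 lower, the first 2 of which were named after their values were seen. The inflammation list had a median of -0.13 (fry adjusted p = 0.983), with Nfkbia at 0.61 and Cxcl12 at -0.29. The renin-angiotensin list, with Ace at 0.28, Atp6ap2 at -0.07 and Agtr1a at -0.37, had a median of -0.02 (0.02 after scaling to one median), and the growth factor list, with Angptl4 at -0.16 and Vegfa at -0.39, of -0.09 (fry adjusted p = 0.945 for each). In none of these 3 lists did a gene pass adjusted over the list alone.

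An unadjusted p under 0.05 was reached by 1100 genes with limma, and scaling libraries to one median called 27 genes, 9 higher and 18 lower, in place of 5 and 31. Fewer genes passed without NS 1 (18), NS 2 (11), NS 4 (23), Lien 13 (21) or Lien 14 (16), a fit of the 2 groups alone called 7, and Kcna5 missed the threshold without NS 2 (adjusted p = 0.0511). Dusp10, Slc25a25, Cldn5, Apold1, Ptger4, Adamts4 and B4galt1 kept their calls in all 15 fits without 1 library. Calls were lost by Atf3 without NS 1 (0.0723), NS 2 (0.0742), NS 3 (0.061) or Lien 14 (0.0705), by Fosl2 without NS 1 (0.0743), NS 2 (0.0606), NS 3 (0.0608), Lien 13 (0.0554) or Lien 14 (0.0705) and by Spry4 without NS 2 (0.0511), Lien 13 (0.0516) or Lien 14 (0.0655). Egr3, Fam172a, Sgk1, Sik1, Spsb1 and Tnks2 each lost theirs in at least 8 of the 15 fits, among them those without NS 2, Lien 12 or Lien 14, with an adjusted p of 0.113, 0.0885, 0.051, 0.0943, 0.117 and 0.107 without NS 2.

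A further question is which genes moved away from NS in AngII and back in Lien. With limma, 1 gene passed in both steps with opposite signs, B3gat2, which was lower in AngII than in NS and higher in Lien than in AngII, and no gene passed in both with the same sign. Between independent lists 0.00103 such genes would be shared by chance, and 2 of 100 simulations of unchanged groups gave 1. The log2 fold changes of both steps correlated across all genes at r = -0.50 (genes are not independent replicates), against -0.53 ± 0.17 (SD) in the simulations, since both steps share the AngII libraries. The covariance was -0.0634, against -0.0717 ± 0.0442 simulated. When the AngII libraries were divided so that each step used its own, r had a median of -0.04 over the 10 divisions (-0.20 to 0.22). No gene moved back in any of them. Most divisions called no gene in AngII against NS, with 2 AngII libraries in that step, so a gene could not move back there. Without AngII 6, AngII 7, AngII 10, Lien 14 or Lien 15, and without AngII 9 for the second step alone, B3gat2 no longer passed in both steps, and without AngII 9 another gene moved back in its place.

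Of the 12 genes that passed in AngII against NS, 8 also passed in Lien against NS with the same sign, 7 lower (Adamts4, Bcl6b, Dlc1, Dusp10, Irs2, Spry4 and Tcf15) and 1 higher (Kcna5). Both comparisons use the same NS libraries, and how much of this overlap comes from the shared controls was not tested.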

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

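The tests of B4galt1, of the libraries that differ in Hox genes, of endothelial cells and handling for the MAPK genes, and the regroupings for the lists in AngII against NS were chosen after the results were seen, and some were revised after a first run. The other regroupings and the test of the MAPK genes with the Hox covariate were set down before their results.

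Single libraries stood far from the other 4 of their group in 33 of the 342 groups of values examined, where chance gives about 1 in 20, or 17.1. Lien 11 held 14 of them. Its list means were 3.32 for inflammation, 7.00 for complement, 6.41 for glucocorticoid response, 6.69 for oxidative phosphorylation, 6.16 for fatty acid oxidation, 5.07 for lipogenesis, 2.44 for T cells, 3.74 for brown adipocytes and 4.33 for nerve. Its FPKM were 12.2 for Cdk17, 116 for Mapk3, 190.5 for Pdk4, 11 for Tgfbr1 and 49.2 for Tgfbr2.

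In NS, NS 3 stood apart with list means of 9.41 for skeletal muscle and 4.91 for lipogenesis and with 13.2 FPKM of Tnks2, NS 2 with 2.98 for T cells, NS 1 with 3.22 for Y chromosome genes and NS 5 with 23.7 FPKM of Spsb1. In AngII, AngII 8 stood apart with 5.63 for cardiomyocytes, 2.44 for mesothelium and 8.28 for oxidative phosphorylation, and with 0.261 FPKM of B3gat2 and 126.7 FPKM of Mapkapk2. AngII 9 had 6.35 for skeletal muscle, 3.67 for neutrophils and 14.4 FPKM of Crbn, and AngII 10 had 5.04 for oxidative stress, 218 FPKM of Dusp1 and 5.00 FPKM of Mapk8. In Lien, Lien 13 had 246 FPKM of Tagln and Lien 15 had 6.26 FPKM of Dusp10.

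Assembled transcripts without a public identifier took no part in the gene comparisons. Tested with limma beside all transcripts, 1 of them was called in AngII against NS, 1 in Lien against AngII and 4 in Lien against NS, all lower in the first-named group.

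B4galt1 was higher in every Lien library than in every other, and an unnamed assembled transcript was at 25.3 to 31.7 FPKM outside Lien and at 0 to 2.32 in Lien. Differing amounts of skeletal muscle and fat are argued against as the whole cause, since B4galt1 kept a log2 difference of 2.35 from AngII with covariates for both. These covariates do not cover other tissues. When the unnamed transcript was added to B4galt1, the difference became -0.38 (SE 0.09), so fragments of B4galt1 may have been assigned to that transcript outside Lien. Added to Nr1d1, the same transcript brought a difference of 1.41 to -0.08. It has no position in the sources used here, so this assignment and a change of B4galt1 in the Lien group cannot be told apart.

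The MAPK feedback and early genes had a median log2 of -0.56 over all 26 tested in Lien against NS and of -1.51 over the 6 that passed. With the Hox covariate these medians were -0.52 and -1.48 and 6 of 6 passed. The 6 had been selected by their call in this comparison, so they add no support. The posterior Hox mean was 1.05 ± 0.95 in NS and 0.89 ± 0.65 in Lien (SD, n = 5 each), so the covariate could move the difference little. This fit therefore does not decide on a different level of the vessel as the cause. The endothelial list as a set changed little, but this does not decide whether endothelial cells were lost. Its mean was 4.85 ± 0.20 in NS and 4.74 ± 0.14 in Lien (log2 scale, SD, n = 5 each). Its median log2 was -0.065 (bootstrap SE 0.058 over 15 genes, 11 of them lower). Single endothelial genes spread more widely (SD 0.50), a spread that reaches -0.56, and Cldn5 of this list was itself called lower. A loss of endothelial cells is therefore neither argued for nor against. Less induction by handling (median -0.34, SD 0.23, for Fos, Egr1, Jun, Junb, Ier2 and Dusp1) cannot be told apart from a change in MAPK output, since this median lies within its SD of -0.56. The time of day of collection is not given in the sources used here and stays open. A lower MAPK output in the Lien group is a hypothesis that phosphorylated kinases in the same tissue could test, which were not analysed here. Since Dusp10 and Spry4 also fell in AngII against NS, a lower output may not belong to Lien itself. Both comparisons share the NS libraries, however, and what this sharing adds was not tested.

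The 6 libraries highest in the Hox genes of groups 9 to 13 were also the 6 highest in the nerve list (6 of 6 shared), and Th, which makes catecholamines in sympathetic nerves, stood at 13.5 to 107 FPKM in them and at 0 to 6.25 in the other 9. Hox genes of groups 1 to 5 lay at 1.25 to 1.85 in the 6 and at 1.41 to 2.11 in the 9, so NS 3, at 1.25, fell outside the range that a different level of the vessel was taken to require. The brown adipocyte gene Ucp1 stood at 143 to 803 FPKM in the 6 and at 613 to 1921 in the 9. The cardiomyocyte list averaged 0.59 to 1.45 in the 6 and 0.71 to 6.15 in the 9. The 6 thus differed in more than nerve genes, with ranges that overlap those of the 9. A different level of the vessel and nerve tissue left attached to some libraries cannot be told apart, since the labels give no level. The 6 libraries came from 3 groups, which argues against the treatment as the whole cause.

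For the count of genes, 3 of 100 random splits of the libraries (126 are possible), the real one included, called as many as the 12 of AngII against NS. Such a count was uncommon among the splits, but those that reached it besides the real one called 37 and 885. The split that called 885 set NS 1, NS 4, NS 5, AngII 8 and AngII 10 against the others, which is the division by Hox genes and points to a structure of the samples. For Lien against AngII 10 of 100 splits called as many as the real 2, up to 1480, so chance is not excluded. For Lien against NS 1 of 100, the real split, called as many as 36, and the highest other called 4. For B3gat2 as a gene that moved back, 3 of 100 groupings of the 15 libraries, the real one included, gave as many as 1, none more than 1. A count of 1 gene near the floor cannot decide on chance. None of the 10 divisions of the AngII libraries gave a gene that moved back. Most of them called no gene in AngII against NS, where 2 AngII libraries were used, so that result decides nothing.

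For the lists of AngII against NS the regroupings test nothing, since a real count of 0 with fry is reached by any split (100 of 100, highest other 2). There 4 lists had an unadjusted p under 0.05 and camera called 0 with an estimated and 13 with a preset correlation. In both comparisons with Lien chance is not excluded for the number of lists called. Lists of any kind were counted in each split, so the splits do not judge the MAPK feedback list itself. As many as the real 1, the MAPK feedback list, were called in 9 of 100 splits for Lien against AngII (highest other 12) and in 7 of 100 for Lien against NS (highest other 10).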

How the results depend on the processing

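The alternatives with Hox covariates, with cardiac, nerve and lymphocyte covariates, without 3 libraries together, with single transcripts, and with scalings of the lists were chosen after seeing the data. The cause of each change below was not tested, except that a stricter fold change leaves fewer calls by construction. No paired analysis was possible because the groups share no replicate numbers.

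The 12 genes of AngII against NS became 23 with quantile normalization, 6 with scaling to one median, 2 with no filter, 19 with the 2 groups alone, 35 with library weights, 6 with cardiac, nerve and lymphocyte covariates, 6 without NS 3, AngII 9 and Lien 13, and 5 transcripts. Leaving out 1 library gave 1 to 17. The 2 genes of Lien against AngII became 1 with quantile normalization, the 2 groups alone, muscle and fat covariates, Hox covariates, cardiac, nerve and lymphocyte covariates or an absolute log2 fold change of at least 1, 6 with library weights and 4 transcripts, and leaving out 1 library gave 1 to 3. The 36 genes of Lien against NS became 23 with no filter, 7 with the 2 groups alone, 94 with library weights, 20 with cardiac, nerve and lymphocyte covariates, 18 without the 3 libraries and 12 transcripts, and leaving out 1 library gave 11 to 37.

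The 1 gene that moved back became 0 with quantile normalization, the 2 groups alone, each of the 3 covariate fits, an absolute log2 fold change of at least 1 and all 10 divisions of the AngII libraries, and 0 to 1 with 1 library left out. Lists called in AngII against NS went from 0 to 13 with a preset correlation and to 1 with each of the 3 covariate fits, library weights or the 3 libraries left out, and leaving out 1 library gave 0 to 2. The 1 list of Lien against AngII became 0 with an estimated correlation, Hox covariates, cardiac, nerve and lymphocyte covariates, the 3 libraries left out and both scalings, and 8 with a preset correlation, and leaving out 1 library gave 0 to 1. The 1 list of Lien against NS became 12 with a preset correlation and 2 with cardiac, nerve and lymphocyte covariates or the 3 libraries left out, and stayed at 1 with each library left out. The MAPK feedback list passed in 24 of 24 alternatives there and in 8 of 24 in Lien against AngII.

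Of 138 results for single named genes 31 were called, and 5 of these were called under all alternatives run, B3gat2 in AngII against NS, B4galt1 in both comparisons with Lien, and Dusp10 and Slc25a25 in Lien against NS. The other 26 lost the call under at least 1, and none of the 31 changed sign. Of the 107 not called 51 changed sign under at least 1 alternative, 32 of them with a scaling and 38 with a covariate fit, and 11 moved by more than 1 SD. These 107 are judged as values by the SD between replicates, a rule adopted after a stricter one had been tried. Fragment counts can be had only through the steps of low values, so the depth behind values such as those of B3gat2 is known only approximately.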

Other observations

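The choice of lists described here was made after their results were seen, and the lists themselves were fixed in advance. Genes of the circadian clock passed the test that counts change in either direction in all 3 comparisons, with fry either-direction adjusted p of 0.00561 in AngII against NS, 0.0152 in Lien against AngII and 0.00258 in Lien against NS, while the directional adjusted p were 0.347, 0.931 and 0.533. The list passed with a common upward direction in AngII against NS without NS 3 (fry adjusted p = 0.0317), and without NS 3, AngII 9 and Lien 13 together in AngII against NS (0.0189) and in Lien against NS (0.00914). With all libraries it did not pass with camera, at adjusted p of 0.903, 0.922 and 0.645 with an estimated correlation and 0.514, 0.399 and 0.119 with a preset one. Adjusted over the list alone, Per2 (log2 0.72) and Dbp (0.69) were higher in AngII than in NS, Nr1d1 (1.41) was higher and Cry1 (-0.88) lower in Lien than in AngII, and Nr1d1 (1.28) and Dbp (0.73) were higher in Lien than in NS. No clock gene passed over all genes, and those named were chosen after their values were seen.

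Genes of T cells were higher in AngII than in NS for 14 of 14 (median log2 1.08, fry adjusted p = 0.642) and lower in Lien than in AngII for 14 of 14 (median -1.18, fry adjusted p = 0.802), with AngII 7 and AngII 9 the highest libraries. Proliferation genes were higher in AngII than in NS for 18 of 19 (median 0.64, fry adjusted p = 0.444) and lower in Lien than in AngII for 18 of 19 (median -0.34, fry adjusted p = 0.802). Their mean was 2.20 in AngII 7 and 2.44 in AngII 9, against 1.19 to 1.46 in the other 3 AngII libraries and 1.02 to 1.38 in NS. Both lists kept the sign of these medians with both scalings, and neither passed. The mesothelial list, whose genes mark the outer lining of organs, was lower in AngII than in NS for 8 of 8 genes (median -1.18, fry adjusted p = 0.143), with camera adjusted p of 0.119 with an estimated and 7.29e-10 with a preset correlation, and 5 genes were lower adjusted over the list alone. Without AngII 8 the list passed (fry adjusted p = 0.00942).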
